A study of Mus musculus with 2 samples.

How the data were processed

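The series holds 2 single-cell RNA libraries of live-sorted cells from the dorsal upper back of mouse embryos at stage E14.5. Per the labels, tissue of each embryo was digested with collagenase and dispase, red cells were lysed, and 5 control and 6 mutant embryos were pooled by genotype before the sort for live cells. Per the labels, the libraries were made with Chromium Next GEM Single Cell 3' chemistry version 3.1. Per the labels, the authors aligned reads with Cell Ranger Count 7.0.1 to the 10x mouse reference on mm10, with introns not counted. The deposited values are counts of UMIs per gene and barcode, and the authors deposited 1 matrix per library with 32285 genes. The file names of the authors carry the word cellbender, a tool that removes background RNA, but its version and settings are not given in the sources used here. The values were checked to be whole numbers of 0 or more. Raw reads were not analysed here.

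Cells were kept with at least 1000 UMIs, at least 500 genes and under 10% mitochondrial UMIs. Low depth removed 7.34% of control-labelled and 10.8% of mutant-labelled barcodes. Scrublet, run per library through scanpy 1.11.5, marked 4.95% and 9.15% of the remaining cells as doublets at its automatic threshold, against 17.0% and 17.5% expected at 0.8% per 1000 cells, so doublets are likely to remain. Haemoglobin genes took 0.0725% and 0.0409% of UMIs. Counts were scaled to 10000 per cell and log-transformed, and 3000 variable genes were chosen within libraries. Mitochondrial, ribosomal, haemoglobin, sex-linked and cell cycle genes and Gata6 were left out of the variable genes. Cells of both libraries were clustered together on 40 principal components and 20 nearest neighbours with the Leiden method at resolution 1, without batch integration, since library and genotype are the same split. The versions used were python 3.11.15, numpy 2.4.6, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and R 4.3.3 with edgeR 4.0.16.

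The 16 clusters were named from marker sets written before the data were examined, as were the 29 gene lists, the rule for named genes and most of the alternatives tried. A cluster took a name when at least 3 markers of a class were 1.5-fold higher in it and detected in at least 2% of its cells, with a mean log2 fold over its markers of at least 0.5, at least 1 marker among its top 10 genes and no more markers of another class there. These naming thresholds were set after the genes of the clusters and their cells per library had been seen. Clusters 0 and 11 met no class and stayed unnamed, with 8.76% and 12.1% of control-labelled cells and 6.92% and 13.8% of mutant-labelled cells.

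Shares of cells have exact binomial (Clopper-Pearson) intervals, and ratios of shares the exact interval of 2 Poisson counts. Intervals printed for list medians are quantiles over 1000 Poisson redraws of the counts. Those that the alternatives were set against used 200 redraws. For genes, UMIs were summed over the cells of a class and divided by all UMIs of that class, as CPM, with exact Poisson intervals and the ratio of mutant-labelled to control-labelled CPM with its exact interval. All intervals are at 95% and treat UMIs as independent. With 1 library per genotype no p-value, standard error or count of changed genes can be had, and cells are not replicates. A gene met the size rule as higher or lower when the libraries were at least 1.5-fold apart and their intervals did not overlap. Named genes were the 12 highest and 12 lowest by ratio among those past the size rule with at least 200 UMIs over both libraries and at least 20 CPM in either. Mitochondrial, ribosomal, haemoglobin and sex-linked genes and gene models without a name were left out of this choice. From each list described, the 2 members with most UMIs and the 2 with the largest log2 ratio were named, and Gata6, Myf5, Ebf2, Pparg, Myod1, Myog and Xist always. For each list the median log2 ratio was taken over members with at least 20 UMIs, with a prior count of 0.5, where at least 5 members were measured. It was placed among 10000 random lists of the same size and level, as a description only. Classes needed at least 100 cells in each library. A ratio against 0 UMIs was set against a floor of 3 counts over the library. Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs, and also unthinned.

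The gene and list steps were tested on simulated data, Poisson counts drawn for both libraries from the pooled rates of a population, with 200 genes altered by known folds. In the adipogenic class, 98.5% of genes altered 2-fold and 52.2% of those altered 1.5-fold met the size rule, as did 0.134% of unaltered genes, and 95.1% of intervals held the true ratio. The draws and the intervals share the Poisson assumption, so these values check the code and give no error rate for the real libraries. A list lowered by a median log2 ratio of -0.26 was found at -0.23. The other lists were not lowered but could hold some of the 200 altered genes. Their medians reached an absolute value of 0.0706 in all kept cells, 0.144 in the adipogenic class and 0.333 in differentiating muscle. Each value is the largest over these lists in 1 draw, so it gives no range for a single list. Gene coordinates are from GENCODE M21 on GRCm38 (mm10), counted from 1, matched by gene identifier. The annotation release behind the reference of the authors may differ.

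The alternatives were no cell filter, a stricter filter (at least 3000 UMIs, at least 1500 genes and under 5% mitochondrial UMIs), doublets kept, resolutions of 0.5 and 2, variable genes with cell cycle genes and Gata6, a class for each cell from its own markers, other denominators of the shares, TMM scaling, CPM without mitochondrial, ribosomal and haemoglobin genes, means over cells, other count minimums, a prior count of 5, and thinning to 1000 or 4000 UMIs. Alternatives chosen after the data were seen were cells with an Xist UMI and no Y-linked UMI, variable genes also without the adipocyte, thermogenic and adipogenic lists and markers, and cluster 0 counted with the adipogenic class. TMM moved the log2 scale by less than 0.1 in each population except mast cells, where it moved by -0.12.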

Results

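Cells were taken from the dorsal upper back of mouse embryos at stage E14.5, at the level of the forelimbs and with most of the spinal cord and ribs dissected away. The library labelled control came from 5 pooled embryos homozygous for a floxed allele of Gata6, a gene for a zinc-finger transcription factor. The library labelled mutant came from 6 pooled embryos with that genotype and Myf5-Cre, a recombinase driven from a gene of muscle and brown fat precursors. The series title names embryonic brown adipocyte development, so the question is how brown adipocyte precursors and their neighbours differed between the genotypes. The control-labelled table held 22941 barcodes with 59866909 UMIs (unique molecular identifiers, which count captured transcripts) and the mutant-labelled one 24493 barcodes with 58594469 UMIs. After filtering, 20201 control-labelled cells (median 2304 UMIs and 1065 genes) and 19839 mutant-labelled cells (median 2179 UMIs and 1053 genes) remained. With 1 library per genotype there was no replicate check, so no test was run and each value describes these libraries. All intervals are 95% intervals covering counting error only. They are exact binomial for shares and exact Poisson for ratios and for CPM, the UMIs of a gene scaled to all UMIs of the class. Those of list medians are quantiles over Poisson redraws of the counts and need not be centred on the median. The control embryos carried no Cre, so the presence of Cre and the loss of Gata6 cannot be separated. Class names such as adipogenic or fascia stand for clusters that resemble those cells by markers fixed in advance.

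Gata6 itself was higher, not lower, in the library labelled mutant. Over all kept cells it gave 1128 UMIs, or 21.1 CPM (19.9 to 22.4), in the control-labelled library and 2172 UMIs, or 44.6 CPM (42.8 to 46.5), in the mutant-labelled library, a ratio of 2.12 (1.97 to 2.28). Fascia fibroblasts held 561 of the control-labelled and 1255 of the mutant-labelled UMIs, with 70.4 CPM (64.7 to 76.5) against 157 CPM (149 to 166), a ratio of 2.23 (2.02 to 2.47). Gata6 is among the top 10 genes of the fascia cluster, though it was left out of the clustering. In the adipogenic class the ratio was 2.35 (1.98 to 2.80), from 42.1 to 98.9 CPM. In unnamed cluster 0 it was 1.54 (1.27 to 1.88), and in tendon cells 2.81 (1.88 to 4.28). From fewer UMIs it was 2.10 (1.23 to 3.69) in dermal fibroblasts and 2.46 (1.52 to 4.11) in cluster 11. Chondrocytes had 2.69 (1.40 to 5.39), muscle progenitors 2.12 (1.13 to 4.20) and macrophages 3.32 (1.03 to 14.0). In mural, differentiating muscle, Schwann and mast cells it was above 1 with intervals that held 1. In blood endothelial cells it was 0.370 (0.00705 to 4.61). After each cell was thinned to 2000 UMIs, 12.5% (11.1 to 14.0) of control-labelled and 22.7% (20.9 to 24.6) of mutant-labelled fascia cells had a Gata6 UMI, with 954 and 1267 shallower cells left out. Without thinning the shares were 15.7% and 27.0% at median depths of 2363 and 2202 UMIs. In macrophages, with 4 and 13 Gata6 UMIs, the shares were 0.159% and 0.995% when thinned. Without thinning they were 0.445% and 1.37%, at median depths of 2497 and 2349 UMIs. Gata6 lies on chromosome 18 at 11052064 to 11085635 of GRCm38 (mm10), and its last exon starts at 11084315. Reads of this assay come from near the 3' end of transcripts, and the labels do not name the deleted exons, so a UMI from outside the deleted part checks nothing about the deletion.

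**Figure D1:**
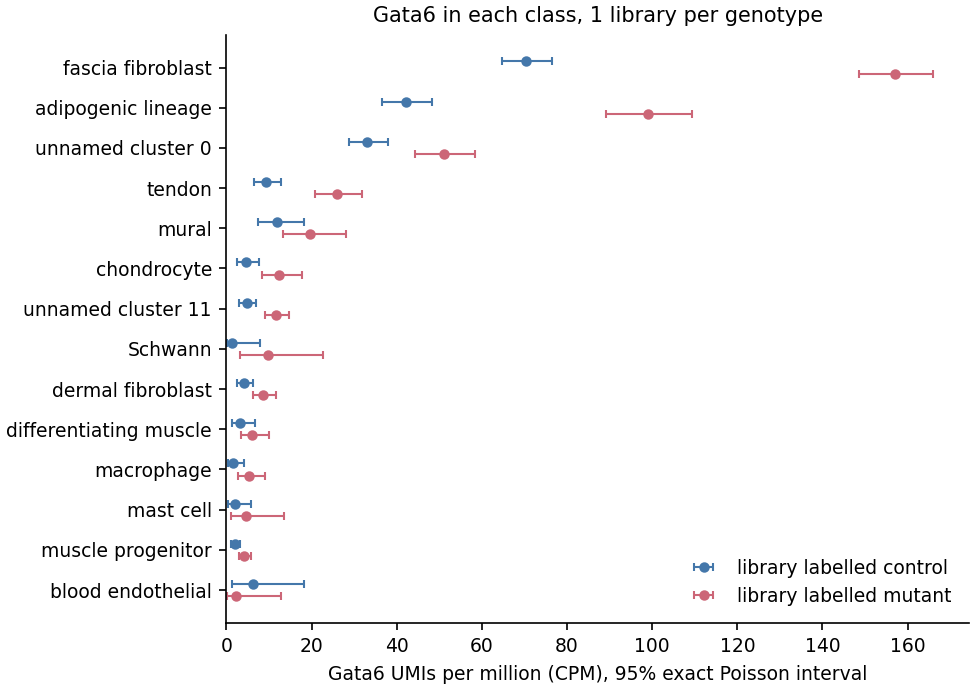
Gata6 level (CPM, x axis) in each class of cells (y axis), with points for the library labelled control and the library labelled mutant and bars for 95% exact Poisson intervals, 1 library per genotype. The fascia fibroblasts read 70.4 CPM in the control-labelled and 157 CPM in the mutant-labelled library, and blood endothelial cells are the only class with the lower value in the mutant-labelled library, from 3 and 1 UMIs.

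Myf5, whose promoter drives the Cre, was lower in the library labelled mutant. It gave 170 UMIs in the control-labelled and 93 UMIs in the mutant-labelled library, a ratio of 0.601 (0.462 to 0.778). Muscle progenitors held 130 and 79 of these UMIs, a ratio of 0.570 (0.425 to 0.759). Myf5 lies on chromosome 10 at 107482908 to 107486134.

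The make-up of the tissue was broadly alike in both libraries. The mast cell cluster, which also held cells with lymphocyte genes, had a smaller share in the library labelled mutant. Schwann cells, chondrocytes and unnamed cluster 0 had somewhat smaller shares there too, and the adipogenic class a slightly smaller one. Differentiating muscle, fascia, muscle progenitors and unnamed cluster 11 had somewhat larger shares. Differentiating muscle (cluster 4) made up 3.38% (3.13 to 3.63) of control-labelled and 4.21% (3.93 to 4.50) of mutant-labelled cells, a ratio of 1.25 (1.13 to 1.38). Fascia fibroblasts (cluster 9) made up 14.7% and 16.5%, a ratio of 1.13 (1.07 to 1.18), and muscle progenitors (clusters 8 and 12) 11.2% and 12.3%, a ratio of 1.10 (1.04 to 1.17). The adipogenic class (cluster 5) made up 9.52% (9.12 to 9.93) and 8.87% (8.47 to 9.27), a ratio of 0.931 (0.873 to 0.994). In this class the median depth was 2286 UMIs in control-labelled and 1955 in mutant-labelled cells, so a filter on UMIs may alter its share. Of its markers, Car3 was itself lower by the size rule in the library labelled mutant, and Fabp4 was lower without meeting that rule. In a clustering without adipocyte genes this class held 1395 control-labelled and 1216 mutant-labelled cells. With a stricter filter (at least 3000 UMIs, at least 1500 genes and under 5% mitochondrial UMIs) the ratio of its shares was 0.359, and with no cell filter the ratio for muscle progenitors was 0.999.

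The mast cell cluster (cluster 1, whose top genes also include the lymphocyte genes Gzma and Trbc2) made up 2.09% and 0.958%, a ratio of 0.457 (0.383 to 0.544). This ratio is therefore not that of mast cells alone. Over all kept cells the mast cell gene Cma1 was found in 356 and 150 cells, Cpa3 in 376 and 198, and Hdc in 311 and 199. Dermal fibroblasts (clusters 2 and 10) had a ratio of 0.9997 (0.942 to 1.06), tendon cells (cluster 15) 0.967 (0.910 to 1.03), macrophages (cluster 7) 1.07 (0.977 to 1.18), blood endothelial cells (cluster 13) 1.03 (0.831 to 1.28) and mural cells (cluster 3) 0.887 (0.780 to 1.01). Schwann cells (cluster 14) had 0.780 (0.667 to 0.912), which was 1.13 with the stricter filter. The top genes of cluster 14 include the melanoblast markers Dct and Pmel, so this ratio may not be that of Schwann cells alone. Chondrocytes (cluster 6) had 0.816 (0.753 to 0.886). At a resolution of 2 the chondrocytes held 572 and 409 cells, a ratio of 0.728 (0.640 to 0.828). An osteoblast cluster found there held 874 and 735 cells, a ratio of 0.856 (0.775 to 0.946). The chondrocyte share also depends on how completely the ribs were removed. Unnamed cluster 0, set apart by replication-dependent histone genes, made up 8.76% and 6.92%, a ratio of 0.790 (0.735 to 0.848). Unnamed cluster 11, set apart by Ngfr and Aldh1a3, made up 12.1% and 13.8%, a ratio of 1.14 (1.08 to 1.21). Within the muscle classes alone, differentiating cells made up 23.2% (21.7 to 24.8) and 25.5% (24.0 to 27.0).

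**Figure D2:**
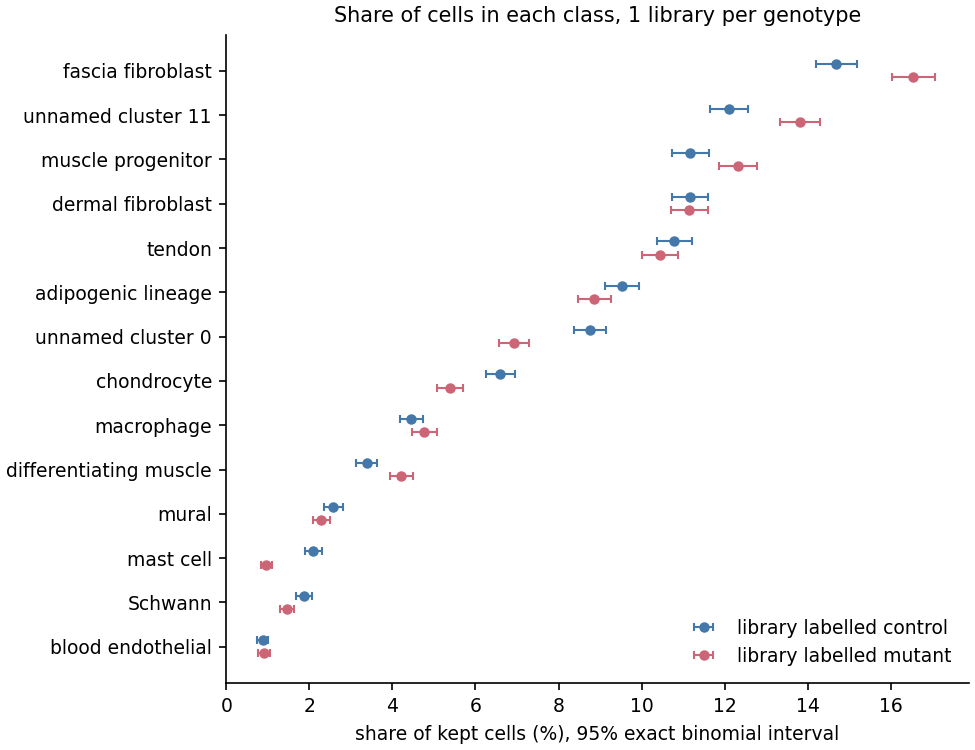
Share of kept cells (%, x axis) in each class (y axis), with points for the library labelled control and the library labelled mutant and bars for 95% exact binomial intervals, 1 library per genotype. Differentiating muscle reads 3.38% in the control-labelled and 4.21% in the mutant-labelled library, and mast cells 2.09% and 0.958%.

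In the adipogenic class, the adipocyte differentiation list was lower in the library labelled mutant, with Car3 and Fabp5 the only members past the size rule. Car3, a carbonic anhydrase abundant in muscle and fat, had 93.2 CPM (84.8 to 102) in the control-labelled and 32.6 CPM (27.1 to 38.9) in the mutant-labelled library, a ratio of 0.350 (0.285 to 0.428). Fabp5, a carrier of fatty acids, had 1020 and 674 CPM, a ratio of 0.662 (0.631 to 0.694). None of the 22 measured members met the rule as higher and 20 met neither. The list median was -0.23 on the log2 scale, lower than every one of 10000 random lists of the same size and level (percentile 0). Such a percentile was not particular to this list. The G2/M and haemoglobin lists of this class also lay at 0 and mitochondrial respiration at 0.02. The imprinted genes lay at 100 and the fibrillar matrix list at 99.89. Slc2a4, a glucose transporter, had 20 and 8 UMIs, a ratio of 0.515 (0.196 to 1.22), and Scd2, a fatty acid desaturase, a ratio of 1.10 (0.961 to 1.26). Other members, chosen after their values were seen, were the lipase Lpl at 0.709 (0.576 to 0.870), the fatty acid transporter Cd36 at 0.717 (0.546 to 0.937), Fabp4 at 0.788 (0.647 to 0.957), Cebpa at 0.7998 (0.594 to 1.07) and Adipoq at 1.498 (1.005 to 2.24). Pparg, the master regulator of fat cell differentiation, had 45.4 CPM (39.6 to 51.7) and 51.0 CPM (44.1 to 58.8), a ratio of 1.13 (0.923 to 1.37). Ebf2, a regulator of brown fat precursors, had 134 and 132 CPM, a ratio of 0.985 (0.875 to 1.11). It was not particular to the adipogenic class. Unnamed cluster 11 had more of it, with 159 and 149 CPM, a ratio of 0.934 (0.847 to 1.03), and cluster 0 had 112 and 121 CPM. Of the 20 measured adipogenic regulators, Hoxc8 alone met the size rule, with 31 and 2 UMIs, a ratio of 0.0831 (0.00964 to 0.327), and the list median was -0.01. Hoxc8 is also in the Hox and body position list and was lower in dermal fibroblasts and over all kept cells too. The thermogenic list had too few measured members in this class and a median of -0.02 over 11 members in all kept cells.

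The adipogenic class also held cells near other types. At a resolution of 2, 19.4% of a fascia cluster and 13.4% of an unnamed cluster came from the adipogenic class, so a different mix of such cells is not excluded as part of the lower list. Car3, Pparg and Fabp4 are among the genes that set the adipogenic cluster apart, which bears on where its border lies. In a clustering without the adipocyte genes, chosen after the data were seen, the list median in the class was -0.25 (-0.39 to -0.04) and the Car3 ratio 0.352. With the stricter filter on UMIs, genes and mitochondrial share the Car3 ratio was 0.770. In cells with an Xist UMI and no Y-linked UMI, a choice also made after the data were seen, the Car3 ratio was 0.225 but the list median only -0.091 (-0.47 to -0.01).

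**Figure D3:**
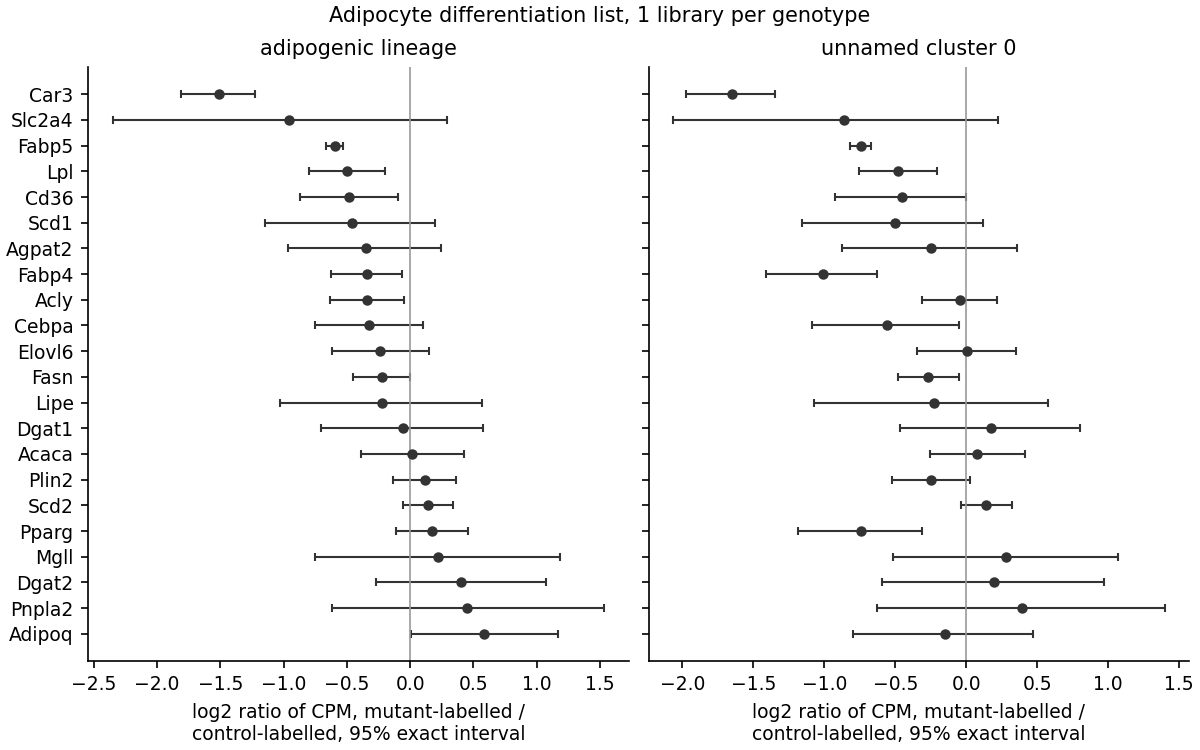
Log2 ratio of CPM, mutant-labelled over control-labelled (x axis), for each measured gene of the adipocyte differentiation list (y axis) in the adipogenic class (left) and unnamed cluster 0 (right), with 95% exact intervals, 1 library per genotype. Car3 lies farthest to the left in both panels, at -1.51 and -1.65.

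Among all genes of the adipogenic class, the 12 with the highest ratios included Gata6, Fst, Cnmd, Col4a5, Trpc5, Sulf1 and Sema6d. Fst, the secreted inhibitor of activins, had 70.5 CPM (63.2 to 78.3) in the control-labelled and 143 CPM (131 to 155) in the mutant-labelled library, a ratio of 2.03 (1.77 to 2.33). Cnmd, an inhibitor of blood vessel growth found in cartilage, had a ratio of 2.43 (1.84 to 3.23), and Col4a5, a basement membrane collagen, 2.15 (1.64 to 2.83). Trpc5, a cation channel, had 1.91, the heparan sulfatase Sulf1 1.85 and the semaphorin Sema6d 1.83. Pus3, Crybg3, Paxbp1, Ly6h and Igfbp6 lay between 1.69 and 1.90. The 12 with the lowest ratios were Car3, Cwc22 at 0.416, Rps6ka3 at 0.437, Car13 at 0.497, Cdk6 at 0.539, Cited1 at 0.600, and Uck2, Tent5a, Aurkaip1, Mt1, Prelp and Chchd4 between 0.606 and 0.622. Car13 and Prelp also help to set this cluster apart. With the stricter filter Igfbp6 had 0.927 and Mt1 1.07, both on the other side of 1. Paxbp1, Cwc22 and Aurkaip1 differed in the same direction in the other classes, with median ratios there of 1.61, 0.566 and 0.638.

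Other lists in the adipogenic class had members past the size rule in either direction. The fascia list had a median log2 ratio of 0.03 over 17 members, with Dpp4 at 1.92 (1.31 to 2.84), Igfbp5 at 1.55 (1.40 to 1.72) and Igfbp6 higher and Dpt lower at 0.622 (0.462 to 0.831). The tendon list had 0.08 over 13 members, with Col14a1 at 1.63 (1.51 to 1.75), Thbs4 at 1.64 (1.16 to 2.33) and Fibin at 1.60 (1.37 to 1.88) higher. The cartilage list had 0.13 over 14 members, with Cnmd and Col9a2, at 1.65 (1.28 to 2.14), higher. The FGF and IGF list had 0.17, with Igf1 at 1.59 (1.49 to 1.70) and Igfbp5 higher among 21 members, and the vascular ligands 0.25, with Cxcl12, at 1.59 (1.43 to 1.76), the 1 higher of 14. The Hox and body position list had 0.02 over 20 members, with Hoxa3, Hoxa4 and Hoxa5 higher and Hoxc8 lower. In 1 simulated draw, the 26 lists other than the adipocyte list reached absolute medians of up to 0.14 in this class. Smaller values are thus of a size seen there. That maximum is over unlike lists that could hold altered genes, so it sets no cutoff for a single list. The Notch list had a median log2 ratio of -0.07 and the retinoid list 0.05. The basement membrane list had a median log2 ratio of 0.21, with Col4a5 the 1 member of 15 past the size rule, and Sparcl1 at 1.24 (1.14 to 1.35). The BMP and TGF-beta list also had 0.21, with Fst the 1 member of 24 past the rule and Id3, a target of BMP signals, at 1.21 (1.08 to 1.34). The imprinted genes had 0.21 with none of 21 past the rule, and Meg3 stood at 1.18 (1.15 to 1.21) and Peg10 at 1.42 (1.24 to 1.63). The fibrillar matrix list had 0.14, with Eln, for elastin, higher at 1.502 (1.25 to 1.80) and Aspn lower at 0.654 (0.536 to 0.796). The nuclear genes of mitochondrial respiration had -0.13, with none of 30 past the rule, Cyc1 at 0.770 (0.683 to 0.868) and Idh3a at 0.706 (0.510 to 0.968). The G2/M list had -0.13, with Cdca3, at 0.635 (0.495 to 0.809), the 1 of 30 members past the rule. Muscle genes had few UMIs in this class. The myogenic list median was 0.37 and Myog, with 24 and 41 UMIs, had a ratio of 2.20 (1.30 to 3.81).

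In unnamed cluster 0, whose best match among the marker sets was adipogenic, Car3 and Fabp5 were lower too, and so were Fabp4 and Pparg. At a resolution of 2 this cluster splits into adipogenic cells (967 control-labelled and 659 mutant-labelled) and tendon cells (806 and 725), so its make-up differs between the libraries. How much of these ratios comes from that make-up was not tested. Car3 had 78.4 and 24.9 CPM, a ratio of 0.318 (0.255 to 0.394), Fabp4 a ratio of 0.497 (0.377 to 0.648), Fabp5 0.598 (0.568 to 0.629) and Pparg 0.598 (0.439 to 0.807). These were the 4 members lower by the size rule among 22 of the adipocyte list, whose median was -0.24. Fst was higher here too, at 1.91 (1.64 to 2.22), with the mitotic genes Aspm at 1.90 (1.57 to 2.29) and Anln at 1.74 (1.52 to 1.99). The G2/M list median was 0.31, and that of the S phase list 0.04.

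In fascia fibroblasts, Pappa, Trpc5, Hpgd, Rspo2, Shox2 and Pcsk5 stood beside Gata6 among the genes with the highest ratios. At a resolution of 2, a fascia cluster with Pappa and Rspo2 among its top genes held 961 control-labelled and 1467 mutant-labelled cells, 63.9% of them from this class. Another held 1072 and 956 cells, 99.8% from this class, and 1 more held 1375 and 1389, 76.4% from it. A different make-up of the class may thus be part of these ratios, which was not tested. Pappa, a protease that frees insulin-like growth factors, had 26.0 and 50.7 CPM, a ratio of 1.95 (1.65 to 2.32). Trpc5 had 2.10 (1.62 to 2.73), the prostaglandin-degrading enzyme Hpgd 1.81 (1.49 to 2.22), the Wnt amplifier Rspo2 1.79 (1.46 to 2.22), the homeobox gene Shox2 1.74 (1.48 to 2.04) and the convertase Pcsk5 1.63 (1.47 to 1.81). The lowest ratios were those of Ssh2 at 0.221 (0.152 to 0.314), Trim2 at 0.335 (0.242 to 0.457), Neat1 at 0.413 (0.350 to 0.486), Spsb1 at 0.489 (0.382 to 0.623), the metallothionein Mt1 at 0.515 (0.458 to 0.578) and Hmga2, a chromatin protein of embryonic cells, at 0.602 (0.486 to 0.744). The adipocyte list was lower here as well, with a median of -0.15 and Car3 the 1 of 21 members past the size rule. The G2/M list had -0.31, with Cdc20 the 1 of 30 members past the rule, at 0.508 (0.384 to 0.668). With cell cycle genes and Gata6 both among the variable genes, the G2/M median was 0.04.

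In tendon cells Fst had a ratio of 1.92 (1.53 to 2.42) and Osr1, a transcription factor of connective tissue, 1.55 (1.24 to 1.96). Neat1 had 0.478 (0.353 to 0.641), and the G2/M list a median of -0.37 with Nusap1 at 0.608 (0.484 to 0.761), which was 1.15 at a resolution of 2. In dermal fibroblasts Hoxc8 had 0.426 (0.331 to 0.545), from 43.1 to 18.4 CPM. The bone gene Ibsp had 2 and 213 UMIs there, a ratio of 114 (31.3 to 951), but 94.0% of these UMIs came from 1 cell. The muscle genes Actc1, at 0.534 (0.401 to 0.706), and Tnnt1, at 0.545 (0.402 to 0.733), were lower in dermal fibroblasts, and with doublets kept both were higher, at 1.16 and 1.17. Over the fascia, dermal and tendon classes together, Gata6 had 2.34 (2.13 to 2.57), Hpgd 1.84, Pappa 1.81, Fst 1.63 (1.51 to 1.77), Rspo2 1.63 and the collagen Col14a1 1.51 (1.46 to 1.56).

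The muscle contractile list was higher over all kept cells of the library labelled mutant, where differentiating muscle also had the larger share, but not within muscle progenitors. In muscle progenitors the contractile list had a median log2 ratio of -0.07 and the myogenic list -0.05. Over all kept cells the muscle contractile list had a median log2 ratio of 0.41, with Neb at 1.53 (1.44 to 1.64), Tnnc1 at 1.53 (1.34 to 1.75) and Casq2 at 1.78 (1.19 to 2.68) past the size rule and 21 of 24 members past neither. The myogenic list had 0.18 over 17 members, with Lbx1 higher, at 27 and 54 UMIs, and Myf5 lower. Myod1 had 9.83 and 13.6 CPM, a ratio of 1.38 (1.23 to 1.55), and Myog 39.2 and 48.9 CPM, a ratio of 1.25 (1.18 to 1.32). Within differentiating muscle the contractile list had 0.15 over 23 members, at percentile 99.99 of its random lists, whose median was 0.035. In the simulated draw the largest absolute median of any list but the adipocyte one was 0.33 there, which gives no range for this list. Myod1 had 1.42 (1.14 to 1.76) in this class and Myog 1.09 (1.01 to 1.17). The G2/M list there had -0.36, with Nusap1, at 0.575 (0.458 to 0.719), and Cdc20, at 0.593 (0.410 to 0.853), past the rule among 30 members and Top2a at 0.710 (0.621 to 0.811). With the stricter filter on UMIs, genes and mitochondrial share that median was 0.02. Other genes with low ratios in this class were Cck at 0.470 (0.390 to 0.566), Akap12 at 0.515, Tshz2 at 0.543, Nfia at 0.544 and Fn1 at 0.626, and those with high ratios included Mapk8ip3 at 1.76, Atp13a3 at 1.63 and Trp53, for the p53 protein, at 1.60 (1.23 to 2.09). With the stricter filter Mapk8ip3 had 0.914 and Fn1 1.05, and at resolution 0.5 Fn1 had 1.02, all on the other side of 1. In muscle progenitors Col12a1 had 1.66 (1.34 to 2.05) and Plekhh2 1.62, while the chaperone Cryab had 0.574 (0.504 to 0.653) and Runx1 0.642. Myog had 0.836 (0.733 to 0.953) in muscle progenitors.

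Over all kept cells the median log2 ratio of the 12054 genes with at least 200 UMIs was 0.04, and most lists lay near it. The adipocyte list had -0.13 over 24 members, with Car3 and Gpd1 lower by the size rule. The cartilage list had -0.31 over 18 members, with Comp at 0.563 (0.511 to 0.619), Hapln1 at 0.605 (0.550 to 0.666) and Matn3 at 0.563 (0.410 to 0.766) lower, beside the smaller chondrocyte share. The bone list had -0.12, the tendon list -0.09, the dissociation stress list -0.07, the hypoxia and glycolysis list -0.06, the p53 list -0.05, the adipogenic regulators -0.04, and the BMP and TGF-beta list -0.03. The fascia list had -0.02, Hedgehog -0.01, mitochondrial respiration 0.01, the S phase list 0.02, and the vascular ligands 0.05. The dermal and Wnt list had 0.06, the retinoid and imprinted lists 0.08, the fibrillar matrix and interferon lists 0.09, Notch 0.10, FGF and IGF 0.11, and basement membrane 0.13. The G2/M list, with 30 members, lay at percentile 3.13 of its random lists and had no member past the rule. The list of GATA factors and partners had -0.26 over 7 members, with Gata6 the 1 higher. The haemoglobin and erythroid list had -2.28 over 8 members, with Hbb-bs at 17618 and 2460 UMIs, a ratio of 0.153, and 6 members lower. In the adipogenic class Hbb-bs had 4038 and 25 UMIs. Background removal that differed between the libraries would alter the ratios within classes, and this was not tested.

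The Hox and body position list had a median of 0.00 over 25 members, and 23 met neither side of the size rule. The 2 that met it were Hoxc8, a gene of the thoracic level, with 537 and 192 UMIs, a ratio of 0.393 (0.331 to 0.464), and Tbx5, a gene of the forelimb level, 29 and 63 UMIs, a ratio of 2.39 (1.51 to 3.84). Xist, the transcript that silences an X chromosome in females, had 405 CPM (400 to 410) and 270 CPM (265 to 275), a ratio of 0.667 (0.652 to 0.681). The pools thus differed in sex mix, beside genotype.

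Some genes differed alike in nearly every class, or in classes where the labels name no Cre activity. Paxbp1 was at least 1.2-fold higher in the mutant-labelled library in all 14 classes with enough counts, with a median ratio of 1.62, as was Mycbp2, with 1.31, and Hspa1b, a heat shock gene, was so in 11 classes, with 1.51. Hist1h4d was lower by as much in 14 classes, with 0.673. Of 7677 genes with at least 50 UMIs in at least 8 classes, these alone were 1.2-fold apart in the same direction in every class with that many UMIs. Gata6 did not reach that count in enough classes to be among the genes looked at. In blood endothelial cells Hist1h1b had 1.90 (1.62 to 2.23), Cavin3 1.66 (1.24 to 2.24) and Fabp4, an abundant gene of capillaries, 1.503 (1.27 to 1.78), and Ccl21a_ENSMUSG00000094686, of lymphatic vessels, had 0.277 (0.216 to 0.352), with 24.7% of its UMIs in 1 cell. The adipocyte list had a median of 0.01 in macrophages, -0.13 in blood endothelial cells, -0.19 in Schwann cells and -0.15 in mast cells. In the other classes it had -0.21 in differentiating muscle, -0.10 in chondrocytes, -0.05 in dermal fibroblasts, -0.04 in mural cells, -0.04 in cluster 11, 0.09 in muscle progenitors and 0.10 in tendon cells.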

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

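All tests in this part were chosen after the results were seen. The Y-linked genes Ddx3y, Eif2s3y and Uty, used here only to choose cells for 1 alternative, were seen in the library labelled mutant alone. Ddx3y had 18.9999 CPM there (925 UMIs), Eif2s3y 9.35 CPM (455 UMIs) and Uty 6.18 CPM (301 UMIs), against 0 UMIs of each in the library labelled control. Against a floor of 3 counts over the library they were at least 339-fold, 167-fold and 110-fold higher. Xist UMIs were found in 59.5% of control-labelled cells, and cells with an Xist UMI and no Y-linked UMI made up 38.4% of mutant-labelled cells. A further Y-linked gene, Kdm5d, had 3 UMIs in the control-labelled and 174 in the mutant-labelled library, a ratio of 63.7 (21.4 to 312). The sex mix of the pools therefore differs. Among cells with an Xist UMI and no Y-linked UMI, the Gata6 ratio was 1.82 in all cells and the Car3 ratio in the adipogenic class 0.225. In the control-labelled library this choice kept 76.9% of cluster 0 cells (median 3204 UMIs) and 52.1% of tendon cells (median 1570 UMIs). It thus also shifts the mix of classes, and may shift depth, so it does not set sex alone apart.

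Gata6 UMIs were higher in the library labelled mutant, at a ratio of 2.12. A larger share of Gata6-rich classes is argued against, since the class shares alone would give a ratio of 0.974. Free RNA left in the counts is argued against. The excess of Gata6 in fascia cells was 86.7 CPM, while macrophages of that library had 5.27 CPM (upper bound 9.01). These values do not bear on background removal that took unlike amounts of Gata6 from the libraries, which was not tested. Swapped labels cannot be told apart from correct ones, because Myf5 was lower in muscle progenitors of the mutant-labelled library, at 0.570 (0.425 to 0.759), but the labels do not say that the driver removes Myf5 sequence. A difference in the regulation of Gata6 transcripts stays open, untested, since the labels do not name the deleted exons.

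The adipocyte differentiation list was lower in the adipogenic class of the library labelled mutant, at -0.23. Class borders drawn with the list's own genes are argued against, since in a clustering without these genes the median was -0.25 (-0.39 to -0.04). A shift in every cell type is argued against, since the median in macrophages was 0.0077 (-0.095 to 0.18), but one shared by some types stays open, with -0.19 (-0.46 to 0.05) in Schwann and -0.13 (-0.34 to 0.28) in blood endothelial cells. A different sex mix stays open, since in cells with an Xist UMI and no Y-linked UMI the median was -0.091 (-0.47 to -0.01). Genotype may account for the lower list, but with 1 library each it cannot be told apart from any other difference between the pools. These include the sex of the embryos and the levels of the body position genes Hoxc8 and Tbx5, which also differed over all kept cells. A different mix of neighbouring cells in the class stays open, untested.

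The share of differentiating muscle was higher in the library labelled mutant, at a ratio of 1.25. Among cells with an Xist UMI and no Y-linked UMI the ratio was 1.12 (0.957 to 1.31), which leaves a different sex mix open. More muscle in the dissected tissue also stays open, since differentiating cells per muscle progenitor had a ratio of 1.13 (1.02 to 1.25), between the value of 1 that this would give and that of the whole share. An effect of genotype stays open, untested.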

How the results depend on the processing

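Alternatives chosen after seeing the data were cells with an Xist UMI and no Y-linked UMI, variable genes also without the adipocyte and adipogenic lists, and cluster 0 counted with the adipogenic class. Over these and the alternatives fixed before the data were examined, of the leading values, 88 stayed within their interval, 21 moved beyond it and 1 reversed; of the other shares, lists and genes, with the named genes of the adipogenic class alone, 495 stayed, 82 moved and 5 reversed. The cause was not tested for any of them. The adipocyte list in the adipogenic class stayed below 0 under each of its 15 alternatives, between -0.09 and -0.32.

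The stricter filter, which left 8309 cells, moved many values. With it the share ratio was 0.359 for the adipogenic class, 1.05 for fascia and 1.29 for muscle progenitors. The Gata6 ratio was then 1.62 in all cells, 1.73 in the adipogenic class and 1.91 in fascia. Over all cells the adipocyte list median was -0.22 and that of the contractile list 0.48. This filter reversed the Schwann share (1.13), G2/M in differentiating muscle (0.015), and Igfbp6 (0.927) and Mt1 (1.07) in the adipogenic class. Among named genes of other classes it reversed Actc1 (1.36) and Tnnt1 (1.65) in dermal fibroblasts and Mapk8ip3 (0.914) and Fn1 (1.05) in differentiating muscle. Actc1 and Tnnt1 also reversed with no filter (1.07 and 1.41) and with doublets kept (1.16 and 1.17), Fn1 at resolution 0.5 (1.02), and in tendon Nusap1 (1.15) and Dbf4 (1.05) at resolution 2 and Nusap1 (1.06) with cell cycle genes and Gata6 as variable genes. Without a filter the muscle progenitor share reversed, to 0.999. The adipogenic share ratio was 0.834 at resolution 2 and 0.864 with cluster 0 added. The fascia share ratio was 1.21 with cell cycle genes and Gata6 as variable genes, where G2/M in fascia reversed (0.039), 1.18 without adipocyte genes and 1.02 with classes per cell. The differentiating muscle share ratio was 1.12 at resolution 0.5 and 1.12 in cells with an Xist UMI and no Y-linked UMI. Those cells gave Gata6 ratios of 1.82 in all cells and 1.87 in the adipogenic class, where resolution 2 gave 1.95 and classes per cell 1.91. As a mean over cells, Gata6 was 2.28 and the adipocyte list -0.066 in all cells. Resolution 0.5 gave no adipogenic class, no filter no Schwann or mural class, and the stricter filter no tendon class. With no UMI minimum, 11 of 24 named genes stayed named in the adipogenic class, 24 of 24 in fascia and 2 of 22 in differentiating muscle. In simulated data 52.2% of genes altered 1.5-fold in the adipogenic class met the size rule, and 53.7% over all kept cells. A gene altered by just the 1.5-fold of the rule can thus miss it at either depth.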

Other observations

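The values in this part were chosen after they were seen. Values for blood cell genes are over all kept cells, so they include the smaller share of the mast cell cluster in the library labelled mutant. Gzma, a protease of killer lymphocytes, had 835 UMIs in the control-labelled library and 0 in the other, at least 253-fold lower against a floor of 3 counts. The T cell receptor genes Cd3g, with 480 and 16 UMIs, and Cd3d, with 183 and 2 UMIs, had ratios of 0.0366 (0.0208 to 0.0601) and 0.012 (0.00144 to 0.044). The mast cell proteases Cma1 and Tpsb2 had 0.423 (0.400 to 0.447) and 0.372 (0.333 to 0.414), and Mcpt4 242 and 8 UMIs. Other mast cell genes were less far apart, with Cpa3 at 0.690 (0.659 to 0.724), Hdc at 0.649 (0.597 to 0.706) and Gata2 at 0.779 (0.664 to 0.912). Gzma was found in 164 control-labelled and 0 mutant-labelled cells, of which 127 lay in the mast cell cluster. The neutrophil genes S100a8 and S100a9 had 0.211 (0.190 to 0.234) and 0.144 (0.130 to 0.159), with 13.9% and 16.7% of their UMIs in 1 cell. S100a8 was found in 95 control-labelled and 52 mutant-labelled cells, and S100a9 in 49 and 51. The macrophage genes C1qa and Mrc1 had 1.13 (1.07 to 1.18) and 1.23 (1.17 to 1.30).

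At a resolution of 2, a cluster of adipogenic cells with histone genes, of which 97.4% came from unnamed cluster 0, held 967 control-labelled and 659 mutant-labelled cells, a share ratio of 0.694 (0.628 to 0.767). Car3, which differed between the libraries, is among its top genes. A cluster of tendon cells with histone genes, also from cluster 0, had 806 and 725 cells, a ratio of 0.916 (0.827 to 1.01). A fascia cluster set apart by Tnxb, Sfrp1, Prss35, Pappa, Igf1, Col14a1 and Rspo2 held 961 and 1467 cells, a ratio of 1.55 (1.43 to 1.69), and Pappa, Col14a1 and Rspo2 were themselves higher in fibroblasts of the mutant-labelled library.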
